A study of Mus musculus with 6 samples.

How the data were processed

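The data were 6 Affymetrix arrays of total RNA from mouse splenic CD8+ T cells cultured as Tc1 or Tc17, with biotin-labelled RNA and 3 arrays per group. The deposited values were log2 intensities made by the authors with RMA and Partek, per the submitters' processing notes, which give no versions or roles. The value range fitted log2 intensities. RMA corrects the background, normalizes between arrays by quantiles and summarizes the probes of a probe set. Which arrays were normalized together, the genome build and the annotation release were not given in the sources used here, so no coordinates are printed. No array gives a detection call, so a dim probe set could not be told from one without signal.

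The array titles name biological replicates 1 and 2 in each group and 1 technical replicate 2. The technical array was read as another array of the biological sample numbered 2, and their log2 values were averaged, which left 2 samples per group. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a group mean per condition), with Benjamini-Hochberg adjustment over all 41345 probe sets and a threshold of 0.05. The fit had 2 residual degrees of freedom, to which moderation added 2.63. No probe set was filtered. The plan was to leave out control probe sets, but the annotation at hand does not mark them, so they stayed in the fit. An unadjusted p under 0.05 was found for 5482 probe sets (13.3%), and the median difference over all probe sets was −0.02.

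Probe sets were named from the platform annotation, which gave 1 symbol for 23521 probe sets, several for 1814 and none for 16010. The 46 called probe sets without a name and 13 with several symbols were counted but not named. A gene was represented by its single-symbol probe set with the highest mean over the 6 arrays, which gave 22180 genes, 1082 of them with more than 1 probe set. Of 17 called genes with several probe sets, 4 had another probe set with a difference of the opposite sign, none of them called, and 2 had another called in the same direction. Entrez identifiers matched 21994 genes to the RefSeq table of assembly GRCm38.p6, with 0 differing symbols. That table was used for names and for the order of genes along the chromosomes only.

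The comparison, the test, 33 gene lists and the genes to name were chosen before the data were examined. Named genes were the 12 largest differences in each direction among called genes with non-overlapping arrays, passing over provisional symbols. Added to these were up to 4 called and 2 uncalled members of each list with the largest differences, or all called members where they were 5 or fewer, and 12 genes named whatever their values. Genes without a probe set of 1 symbol, such as Tcf7, were not analysed. Lists were tested at the gene level with limma's camera at a preset correlation of 0.01 against all other genes, again with an estimated correlation, and with fry. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, which raises its p-values whatever the correlation. The camera p-values were adjusted over the 33 lists. Fry, which asks whether a list's genes moved one way on balance without comparing them with other genes, called 14 lists, and its mixed test called 26.

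The procedure was tested on simulated data made for the Tc17 against Tc1 comparison with 41345 probe sets. It recovered 78% of probe sets changed by 1 and 100% of those changed by 2 on the log2 scale, and called 5 unchanged ones. With nothing changed it called 0, and camera called a shifted list and 0 others. Probe sets were drawn independently, with normal noise at the moderated variances of the fit. The list result therefore does not test camera on correlated genes, and the recovery rates hold for that noise only.

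Alternatives were other readings of the technical array (left out, averaged with sample 1, 6 separate arrays, a random block), the replicate number as a block, quantile normalization, median centring and filters on level. Further ones were eBayes with trend and robust settings, an added threshold of 1 on the log2 difference, an unmoderated test, leaving out each biological sample and the mean of a gene's probe sets. A restriction to named probe sets was added after the results had been seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.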

Results

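Gene expression was measured on 6 single-colour Affymetrix arrays in mouse CD8+ T cells driven towards one of 2 effector states. Naive CD8+ T cells from spleen were stimulated through CD3 (antibody at 1 µg/ml) and CD28 (antibody at 3 µg/ml) over 4 days. IL-12 was present for 3 of those days in the cultures called Tc1, the interferon-gamma-producing state. IL-6 and TGF-beta were present instead in the cultures called Tc17, the IL-17-producing state, and both received IL-2 on the remaining day. Each group had 2 biological samples, and the sample numbered 2 was also represented by a technical array, giving 3 arrays per group. The values were RMA log2 intensities of 41345 probe sets, and the array medians lay between 6.04 and 6.09. The number of arrays, and with it 2 biological samples per group, limits the precision of every difference.

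The arrays separated by culture condition. The first principal component, which held 57.4% of the variance, placed the 3 Tc1 arrays on one side and the 3 Tc17 arrays on the other. Pearson's r across probe sets, which are not independent replicates, was 0.997 between the sample and technical arrays in Tc1 and 0.996 in Tc17. Between the samples numbered 1 and 2 it was 0.994 in Tc1 and 0.995 in Tc17, and between arrays of different groups it ran from 0.987 to 0.989.

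The comparison asked how Tc17 cells differ in gene expression from Tc1 cells. The cytokine genes Il17f and Il17a were 67.9-fold and 37.0-fold higher in Tc17, and Ifng, which encodes interferon-gamma, was 45.1-fold lower. Il17f (probe set 17221627) rose from 6.22 ± 0.01 in Tc1 to 12.30 ± 0.30 in Tc17 (log2, SD, n = 2), and Il17a from 6.32 ± 0.04 to 11.53 ± 0.50. Ifng (probe set 17237589) fell from 13.00 ± 0.25 to 7.51 ± 0.40 (log2, SD, n = 2). Tbx21, which encodes the type 1 transcription factor T-bet, was 6.90-fold lower, and Prf1, the gene of the pore-forming protein perforin, was 4.74-fold lower.

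In limma's moderated test on 2 against 2 biological samples, 351 of 22180 genes passed an adjusted p of 0.05, 220 of them higher and 131 lower in Tc17. A difference of at least 2-fold was found for 153 of the higher and 105 of the lower genes. In all 351 the 3 arrays of one group lay entirely above the 3 of the other, a separation seen in 23.7% of all probe sets and given by chance in 10% for 6 exchangeable arrays. The technical arrays repeat a sample, and for 2 against 2 samples chance gives 33.3%, against 44.1% of probe sets observed. Over all probe sets, named or not, 418 passed, 263 higher and 155 lower. The count depended on each biological sample: without Tc1 sample 1, Tc1 sample 2, Tc17 sample 1 or Tc17 sample 2 the test called 107, 48, 54 or 125 probe sets, and counts below for samples left out in turn follow this order. It also depended on how the technical array was read, with 2318 called when the 6 arrays were taken as separate samples.

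Folds are ratios of array intensities, and no array gave a detection call. For Itgae, Il21, Gpr15, Ebf1, Lyz2, Ahrr, Me1, Ms4a4b, Esm1, Gbp3 and Gm6637 the dimmer group had a mean below every array median, from 4.85 (Gm6637) to 5.93 (Esm1). Signal above background was not shown there, so their folds and their order by fold hold for intensities and not for transcripts. The same limit applies to the log2 differences printed below for Il9, Il23r, Ccr6 and Cyp1b1, whose Tc1 means were 4.97, 5.16, 5.53 and 5.76. It also applies to the falls of S100a4 and Klrg1, whose Tc17 means were 5.68 and 5.70. An array median is not a measure of background, so folds with a dimmer group just above it are not shown to be transcript ratios either. Among these were Il17f (6.22) and Il17a (6.32) in Tc1 and Havcr2 (6.23) in Tc17.

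Besides the IL-17 genes, 10 other named genes led the increases in Tc17. Cpd, which encodes the peptide-trimming enzyme carboxypeptidase D, was 37.6-fold higher (log2 difference 5.23 ± 0.11 SE, limma adjusted p = 0.0018). Itgae, the CD103 integrin chain that binds E-cadherin, was 36.4-fold higher (5.19 ± 0.10, limma adjusted p = 0.00162). Ahr, the gene of a ligand-activated transcription factor, was 21.8-fold higher, and Foxp3, the lineage factor of regulatory T cells, 15.5-fold higher. The cytokine gene Il21 was 19.1-fold higher, and Timp1, which encodes a metalloproteinase inhibitor, had a log2 difference of 4.25 ± 0.46 (SE, limma adjusted p = 0.0429). Ifngr2, one chain of the interferon-gamma receptor, had a log2 difference of 4.00 ± 0.16 (SE). Slc15a1 (a peptide transporter), Pdpn (podoplanin) and Gpr15 (a receptor for homing to the colon) were 14.2-fold, 13.9-fold and 12.8-fold higher.

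After Ifng, 11 other named genes led the decreases. Havcr2, which encodes the inhibitory receptor TIM-3, was 32.5-fold lower (log2 difference −5.02 ± 0.37 SE, limma adjusted p = 0.0182). The serpin genes Serpinb5 and Serpinb6b were 31.7-fold and 25.3-fold lower, and Serpinb9, which encodes an inhibitor of granzyme B, had a log2 difference of −4.00 ± 0.14 (SE). Gzmk, a granzyme gene, was 16.8-fold lower, and Sytl2, a gene of granule docking, 16.1-fold. Ly6c2, part of the Ly6C surface antigen, was 19.4-fold lower and Gbp7, an interferon-inducible GTPase gene, 16.3-fold. Me1 (malic enzyme), Ms4a4b and Esm1 were 17.4-fold, 13.4-fold and 13.3-fold lower. Provisional symbols were passed over; among them Gm6637, picked after its value was seen, was 42.1-fold lower.

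**Figure D1:**
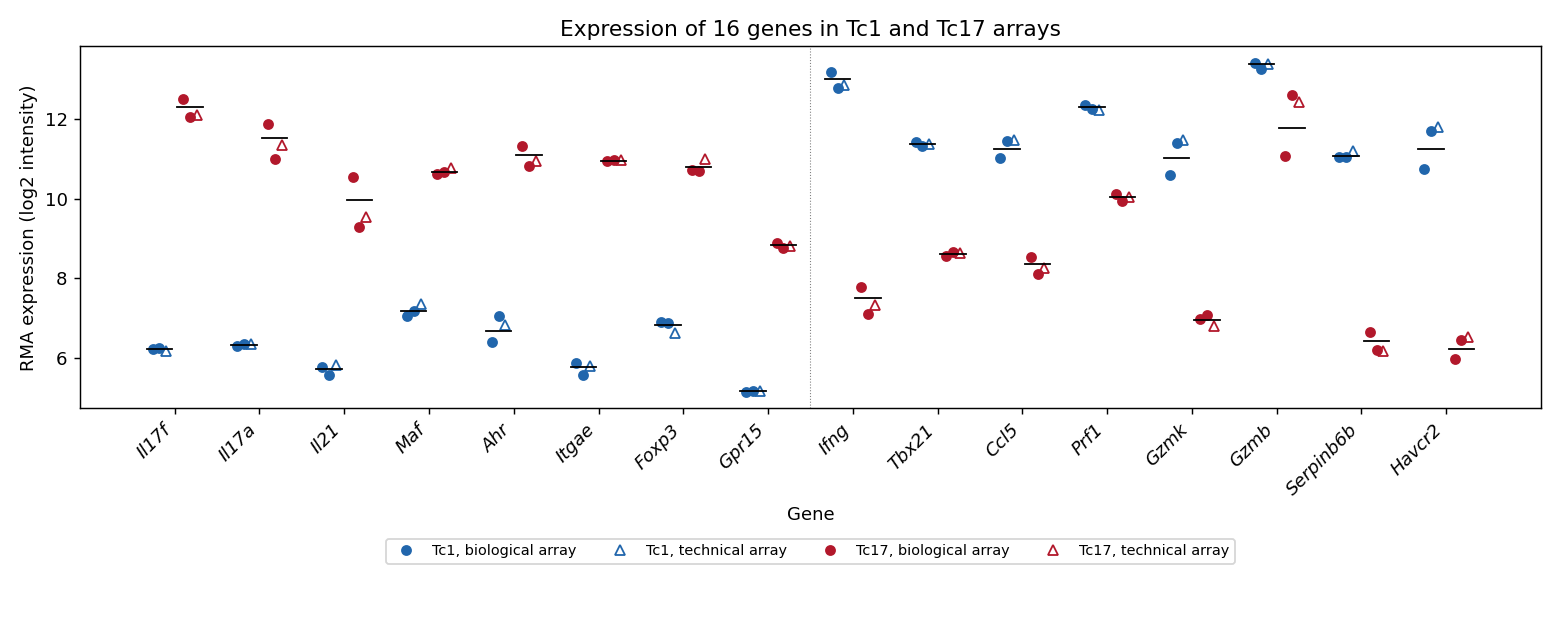
RMA expression (log2 intensity, vertical axis) of 16 genes on the 6 arrays, with Tc1 in blue and Tc17 in red; filled circles are biological arrays, open triangles are technical arrays and black bars are group means of 2 biological samples. The arrays of each group lie apart for every gene, and Gzmb, whose Tc17 arrays spread from 11.07 to 12.60, is the one that did not pass the test.

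Genes of the type 17 programme were higher in Tc17 as a group. Of 15 measured members, 5 rose (13 higher adjusted over the list alone, and 3, 4, 5 and 9 over all probe sets leaving out each sample in turn), namely Il17f, Il17a, Ahr, Il21 and Maf, and all 15 differences were above 0. Among the 15, Il22 (3.02 in Tc1 and 3.08 in Tc17) and Ccl20 (5.94 and 5.96) lay below every array median in both groups. Their differences of 0.06 and 0.02 (limma adjusted p = 0.827 and 0.952) show no rise. Maf, a transcription factor gene, was 11.4-fold higher. The median log2 difference was 2.38, with a camera adjusted p of 1.6e-15 and an adjusted p of 0.236 with an estimated correlation. Il23r, the IL-23 receptor gene, had a log2 difference of 1.59 that did not pass (limma adjusted p = 0.295). It measured 7.50 in Tc17 sample 1 and 6.06 and 5.95 on the arrays of Tc17 sample 2. Il9 and Ccr6 had log2 differences of 3.17 and 2.07 and adjusted p of 0.0661 and 0.0505. In the same arrays the macrophage and monocyte markers had a median log2 difference of 0.27.

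The type 1 programme had a median below 0 in Tc17. Ifng, Ccl5 and Tbx21 fell, 3 of 17 measured members (1 higher and 9 lower adjusted over the list alone, and 5, 2, 2 and 2 lower leaving out each sample in turn), and none rose. Ccl5, a chemokine gene, was 7.32-fold lower and Tbx21 changed by −2.79 ± 0.08 (SE) on the log2 scale. The list's median log2 difference was −0.63 (camera adjusted p = 1.87e-05; adjusted p = 0.236 with an estimated correlation). Eomes, the gene of a T-box factor related to T-bet, had a log2 difference of −1.18 that did not pass (limma adjusted p = 0.0583). The IL-18 receptor genes Il18r1 and Il18rap had log2 differences of −2.47 and −2.27 and did not pass either.

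Cytotoxic effector genes were the group with the lowest median difference of all fixed lists, −1.31. Of 21 measured members 8 fell and none rose (3 higher and 14 lower adjusted over the list alone, and 4, 3, 4 and 6 lower leaving out each sample in turn). Among the called members the largest differences were those of Serpinb6b, Gzmk, Serpinb9 and Prf1, the last from 12.30 ± 0.09 to 10.06 ± 0.08 (log2, SD, n = 2). The camera adjusted p was 4.39e-08, and the adjusted p was 0.236 with an estimated correlation. Gzmb, Gzma and Gzmc had log2 differences of −1.59, −2.48 and −3.09 and did not pass (limma adjusted p = 0.284, 0.308 and 0.0951). Their Tc17 samples differed: Gzmb measured 11.07 in sample 1 against 12.60 and 12.43 on the arrays of sample 2. Gzma measured 7.18 in sample 1 against 9.55 and 9.63, and Gzmc 6.13 against 7.68 and 7.55.

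TGF-beta response genes had a median above 0 in Tc17, the condition cultured with TGF-beta. Itgae, Ldlrad4, Pmepa1 and Tgfbi were among the 6 of 21 members that rose, and none fell (16 higher and 1 lower adjusted over the list alone). With each sample left out in turn 1, 1, 1 and 2 rose, and Ldlrad4 and Tgfbi passed in none of the 4 such fits. Ldlrad4 and Pmepa1, both encoding inhibitors of TGF-beta signalling, were 10.7-fold and 5.51-fold higher. The median log2 difference was 0.64 (camera adjusted p = 2.03e-10; adjusted p = 0.236 with an estimated correlation). Skil and Id3, with log2 differences of 1.28 and 1.21, did not pass.

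Among 16 IL-6 and STAT3 response genes, Il21, Maf and Il6ra rose and none fell (6 higher and 4 lower adjusted over the list alone, and 1, 1, 2 and 2 higher leaving out each sample in turn). Il6ra, a chain of the IL-6 receptor, was 6.37-fold higher. The median log2 difference was 0.33 (camera adjusted p = 0.0232; adjusted p = 0.356 with an estimated correlation). This call ended without Tc1 sample 1 or 2, under both filters on level and with the mean of a gene's probe sets (camera adjusted p = 0.071 to 0.0874). Prdm1 and Il10 had log2 differences of −2.38 and −1.81 and did not pass (limma adjusted p = 0.0621 and 0.0625).

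The aryl hydrocarbon receptor axis had a median above 0. Ahr and Ahrr, the gene of its repressor, rose, 2 of 7 measured members (3 higher adjusted over the list alone, and 2, 1, 0 and 1 leaving out each sample in turn), and Ahrr was 3.51-fold higher. All 7 differences were above 0, with a median of 0.51 on the log2 scale (camera adjusted p = 1.24e-04; adjusted p = 0.236 with an estimated correlation). The median was 0.16 without Tc1 sample 1, 0.19 without Tc17 sample 2, 0.23 with the mean of a gene's probe sets and 0.79 under both filters on level. Cyp1b1 and Tiparp, target genes of the receptor, had log2 differences of 0.79 and 0.51 and did not pass. Tiparp had a difference of −0.05 without Tc1 sample 1, and −0.04 on its other probe set.

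Of 22 measured chemokine receptors and homing molecules 6 rose in Tc17 and none fell (7 higher and 1 lower adjusted over the list alone, and 4, 2, 2 and 4 higher leaving out each sample in turn). Besides Itgae and Gpr15 these were Ccr4 (5.77-fold), Ccr8 (4.46-fold), Cxcr5 (4.46-fold) and Ccr7 (3.04-fold), the last 2 not called after quantile normalization. The median log2 difference was 0.21 (camera adjusted p = 1.87e-05; adjusted p = 0.236 with an estimated correlation). Ccr2 and Cxcr6 had log2 differences of −1.46 and −0.96 and did not pass. Among 16 tissue residency genes Itgae, Ahr and Cd101 rose (6 higher and 5 lower adjusted over the list alone). Their median was 0.09, with 0.02 without Tc1 sample 1, 0.05 without Tc1 sample 2 and 0.03 without either Tc17 sample. Camera against other genes gave an adjusted p of 0.305, and fry called the list up (adjusted p = 0.0066). Cd101, a surface glycoprotein gene, was 10.7-fold higher.

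Of 24 cytokine genes, 5 rose, among them Il17f, Il17a and Il21, and Ifng fell (10 higher and 3 lower adjusted over the list alone, and 2, 1, 4 and 5 higher and 2, 1, 1 and 1 lower leaving out each sample in turn). The median log2 difference was 0.20 (camera adjusted p = 0.0030; adjusted p = 0.283 with an estimated correlation). It was 0.06 without Tc1 sample 2, 0.36 without Tc17 sample 2 and 0.87 under both filters on level.

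Memory and stem-like genes and effector differentiation genes had medians of opposite sign. Cxcr5, Ccr7 and Bach2 rose among 19 memory and stem-like genes and none fell (4 higher and 2 lower adjusted over the list alone, and 1, 0, 0 and 1 higher leaving out each sample in turn). Bach2, a transcriptional repressor gene, was 2.66-fold higher. That list's median was 0.16, with 0.09 without Tc1 sample 1 and 0.25 without Tc17 sample 1 (camera adjusted p = 0.0232; adjusted p = 0.413 with an estimated correlation), and the call ended without Tc1 sample 1 or Tc17 sample 2, under both filters on level and with the mean of a gene's probe sets (camera adjusted p = 0.0799 to 0.27). With quantile normalization Cxcr5 and Ccr7 had adjusted p of 0.0502 each in limma's test, which left 1 of the 3 called. Il7r, the IL-7 receptor gene, had a log2 difference of 0.18 and did not pass, and Tcf7 had no named probe set and was not analysed here. Among 17 effector differentiation genes Tbx21, S100a6, S100a4 and Klrg1 fell and none rose (2 higher and 8 lower adjusted over the list alone, and 3, 1, 2 and 2 lower leaving out each sample in turn). S100a6, a calcium-binding protein gene, was 5.14-fold lower. Their median was −0.28, with −0.13 without Tc1 sample 2 and −0.16 without Tc17 sample 1 (camera adjusted p = 1.37e-04; adjusted p = 0.356 with an estimated correlation).

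Inhibitory receptors and exhaustion-linked genes had no common direction. Havcr2 and Entpd1, the gene of the ATP-cleaving ectoenzyme CD39, fell and Tox rose, 3 of 14 (8 higher and 5 lower adjusted over the list alone, and 0 higher and 2, 0, 0 and 0 lower leaving out each sample in turn). The median was 0.32 and the mean −0.05 on the log2 scale, and camera gave the up direction with an adjusted p of 0.294. The ectoenzymes that turn extracellular ATP into adenosine moved in opposite directions: Entpd1 was 4.11-fold lower and Nt5e, the gene of CD73, 5.81-fold higher. These were the calls among 7 genes of extracellular ATP and adenosine (1 higher and 3 lower adjusted over the list alone, and 1, 1, 0 and 0 higher and 1, 0, 0 and 0 lower leaving out each sample in turn). The median was −0.03 (camera adjusted p = 0.451), and −0.20, −0.03, 0.12 and −0.32 leaving out each sample in turn.

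Interferon-stimulated genes had a median below 0 in Tc17. Gbp3, Igtp, Irf1, Tap1 and Psmb9 fell among 23 measured members and none rose (1 higher and 11 lower adjusted over the list alone). With each sample left out in turn 1, 0, 0 and 0 were lower, and none of these 5 genes passed in any of the 4 such fits. Gbp3 and Igtp, both GTPase genes, were 5.52-fold and 2.83-fold lower, and Tap1, a peptide transporter gene of antigen presentation, 2.12-fold. The median log2 difference was −0.39 (camera adjusted p = 1.07e-07; adjusted p = 0.236 with an estimated correlation). Usp18, with a log2 difference of −3.64, did not pass (limma adjusted p = 0.0755).

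In the fixed cell cycle and metabolic lists 1 gene, Acadl, passed. None of 30 cell cycle genes passed, 28 of their differences were below 0 and the median was −0.23 (0 adjusted over the list alone). Their camera adjusted p was 7.15e-08, and the adjusted p was 0.356 with an estimated correlation. None of 25 oxidative phosphorylation genes passed (0 adjusted over the list alone), with a median of −0.10, with −0.06 without Tc1 sample 1 and −0.17 without Tc1 sample 2 (camera adjusted p = 0.00349; adjusted p = 0.528 with an estimated correlation). Without Tc1 sample 1 or Tc17 sample 2 that camera adjusted p was 0.188 or 0.0714. None of 19 cholesterol synthesis genes passed (4 lower adjusted over the list alone), with a median of −0.13, with −0.07 without Tc1 sample 2 (camera adjusted p = 7.12e-04; adjusted p = 0.522 with an estimated correlation). None of 19 glycolysis genes passed (0 adjusted over the list alone); median and mean were below 0 at −0.0055 and −0.0028, and camera gave the up direction (adjusted p = 0.918). That median ran from −0.04 to 0.03 over the settings. Acadl, an acyl-CoA dehydrogenase gene, was 1.58-fold lower, the call among 16 fatty acid oxidation genes, with an adjusted p of 0.0502 in limma's test after quantile normalization (1 higher and 1 lower adjusted over the list alone, and 0 leaving out any sample; median 0.04, and 0.03 to 0.07 over the settings; camera adjusted p = 0.233).

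Fasl, the gene of a death ligand, was 2.98-fold lower and was the single call among 16 pro-apoptotic genes (3 lower adjusted over the list alone, and 0 leaving out any sample). That list's median was −0.18, with −0.08 without Tc1 sample 2 and −0.09 without Tc17 sample 1 (camera adjusted p = 0.0277; adjusted p = 0.356 with an estimated correlation), and its camera adjusted p was 0.107 without Tc1 sample 2. No anti-apoptotic gene of 9 passed (1 lower adjusted over the list alone); the median was 0.10 (0.0024 to 0.15 over the settings), the mean −0.0013 and the camera direction up (adjusted p = 0.701). No Wnt and beta-catenin pathway gene of 19 passed (2 higher adjusted over the list alone), with a median of 0.04, from −0.07 to 0.04 over the settings (camera adjusted p = 0.777).

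**Figure D2:**
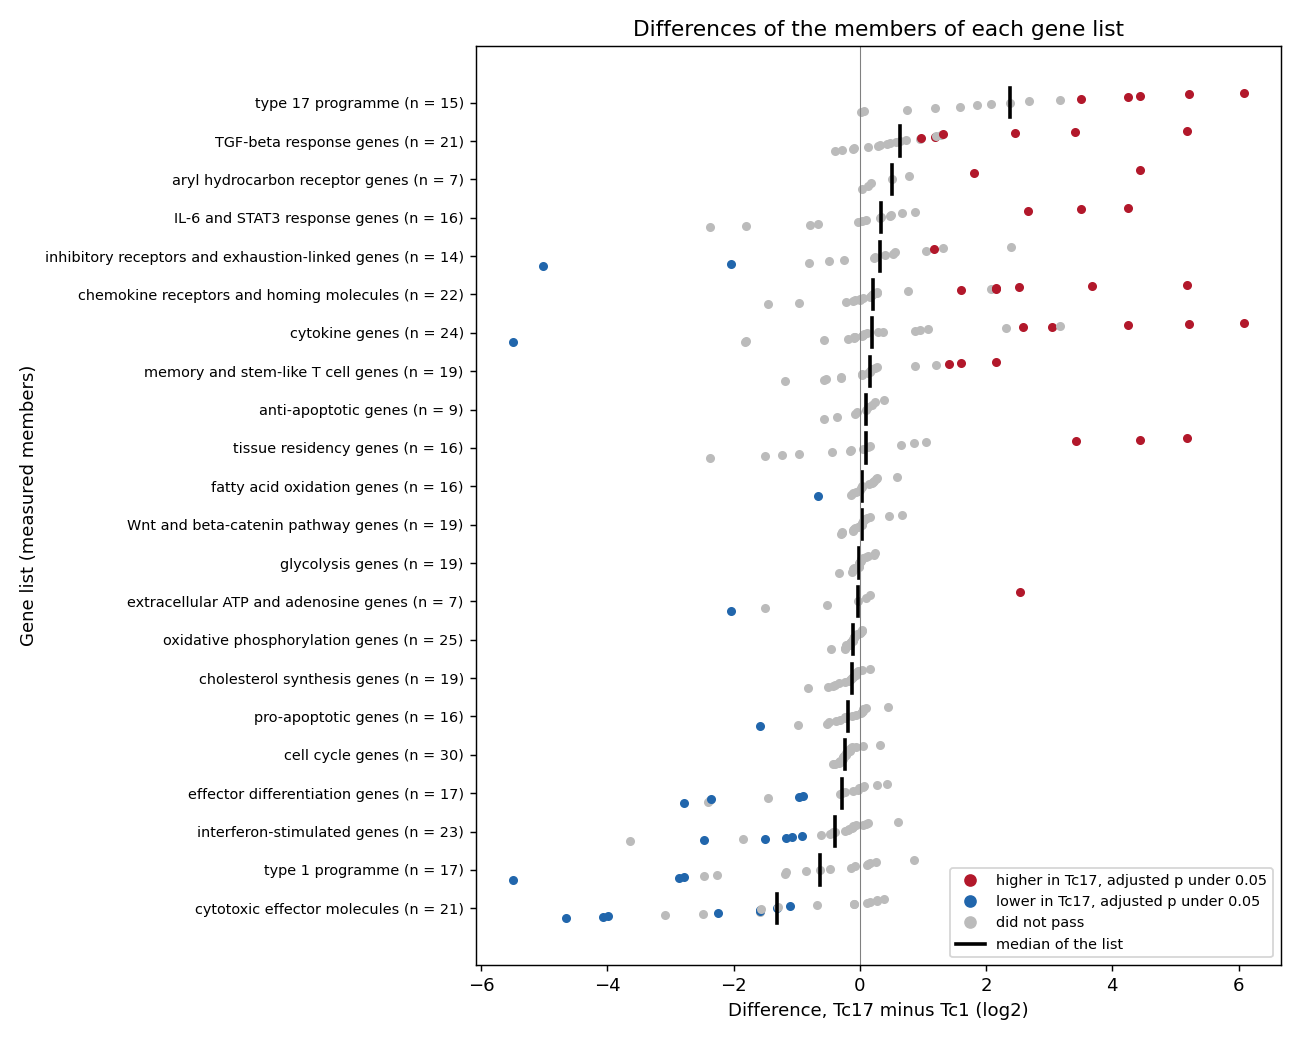
Log2 difference between Tc17 and Tc1 (horizontal axis) of each measured member of 22 gene lists fixed beforehand (vertical axis), in red where higher and in blue where lower at an adjusted p under 0.05, and in grey otherwise; black bars mark list medians. The type 17 programme has the highest median, 2.38, and the cytotoxic effector molecules the lowest, −1.31.

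None of 10 CD8 T cell markers passed (2 higher adjusted over the list alone), with a median of 0.01, from −0.01 to 0.04 over the settings (camera adjusted p = 0.487). Some genes used as markers of other cells were higher in Tc17. Foxp3 and Izumo1r, the gene of folate receptor 4, rose among 6 CD4 and regulatory T cell markers (2 higher adjusted over the list alone, and 2, 1, 1 and 1 leaving out each sample in turn). That list's median was −0.09 (−0.15 to 0.05 over the settings), its mean 0.76 and its camera direction up (adjusted p = 0.230). Lyz2, the lysozyme gene of myeloid cells, was 11.5-fold higher and was the call among 10 macrophage and monocyte markers (2 higher adjusted over the list alone, and 0 without Tc1 sample 2). Their median was 0.27, with 0.10 under both filters on level (camera adjusted p = 1.85e-04; adjusted p = 0.522 with an estimated correlation). Ebf1, a B cell transcription factor gene, was 8.73-fold higher and was the call among 9 B cell markers (2 higher adjusted over the list alone; median 0.01, from −0.02 to 0.17 over the settings, camera adjusted p = 0.199). Ly6g, a granulocyte antigen gene, was 5.74-fold higher and was the call among 7 granulocyte markers (1 higher adjusted over the list alone, and 0 without Tc1 sample 1 or 2; median 0.01, from −0.02 to 0.05 over the settings, camera adjusted p = 0.325).

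In the remaining lists no member passed over all probe sets. They held 5 dendritic cell markers (median 0.08, camera adjusted p = 0.545), 3 gamma delta and innate-like T cell markers (−0.07, 0.340), 4 sex-linked genes (0.03, 0.624) and 8 reference genes (−0.04, 0.233), with 0 in each adjusted over the list alone. Among 5 NK cell markers 1 was higher and 1 lower adjusted over the list alone; the median was 0.01, the mean −0.01 and the camera direction down (adjusted p = 0.701). Among 5 erythroid and platelet markers the median was −0.05, the mean 0.07 and the camera direction up (adjusted p = 0.608; 0 adjusted over the list alone). Over the settings the medians of these 6 lists lay between −0.14 and 0.15, and those of all but the gamma delta and reference lists took both signs. The fixed lists shared members, so their calls are not separate findings. Il17f, Il17a and Il21 were in the type 17 and the cytokine lists, and Il21 and Maf in the IL-6 and STAT3 list too. Itgae was in the TGF-beta, tissue residency and homing lists, and Tbx21 in the type 1 and effector differentiation lists. Of the 33 lists, camera called 16, 8 up and 8 down, and none of these 16 calls held with an estimated correlation. On 2 residual degrees of freedom that test gave a lowest unadjusted camera p of 0.0177, for the TGF-beta list at an estimated correlation of −0.05. For lists with an estimate near or below 0, such as this one, type 1 (−0.05) and IL-6 and STAT3 (−0.06), the loss says little about correlation among genes. The estimate was 0.64 for the macrophage list, 0.39 for oxidative phosphorylation and 0.38 for cholesterol synthesis. It was 0.21 for type 17 and 0.20 for cell cycle. In these lists correlation among genes raises the p-value too, and its share in the loss was not tested. Fry called 14 lists in one direction. It left out 5 of camera's 16 (memory and stem-like, oxidative phosphorylation, cholesterol synthesis, cell cycle and macrophage) and added 3, all up (tissue residency, CD4 and regulatory T cell, and B cell). Without Tc17 sample 1 camera also called the CD4 and regulatory T cell list (adjusted p = 0.048) and the B cell list (adjusted p = 0.0233).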

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

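The restriction to named probe sets was chosen after the results were seen, and the other alternatives before. Counts given in threes are probe sets, genes higher and genes lower in Tc17 at an adjusted p under 0.05, beside 418, 220 and 131 as reported. Other readings of the technical array called 1581, 730 and 510 (averaged with sample 1), 2318, 1084 and 746 (6 separate arrays) and 2074, 995 and 666 (biological sample as a random block, consensus correlation 0.101). Leaving the technical arrays out called 377, 182 and 125. With the replicate number as a block the counts were 1535, 699 and 442, and no list call changed. The numbers were not taken as pairs, since the labels do not say what they share and there are only 2; deviations of same-numbered samples correlated at 0.313 across probe sets, and the second principal component (17.5% of the variance) set both samples numbered 1 apart from the other arrays, as a hint from the data. Filters on level, which test fewer probe sets, called 635, 324 and 208 (group mean of at least 6) and 648, 336 and 210 (above the median probe set). Restricting the test to named probe sets called 860, 497 and 306, and averaging a gene's probe sets, which tests fewer values, called 531 higher and 343 lower genes. The unmoderated two-sample test called 0, 0 and 0, with a lowest adjusted p of 0.172 and 3968 probe sets at an unadjusted p under 0.05, against 5482 with limma. Leaving out 1 biological sample, so that the lone sample of a group is assumed to vary like the other group, called 48 to 125, 25 to 69 and 17 to 45, from 3 samples in place of 4. The share of called genes that were higher, 62.7%, was 51.1% without Tc1 sample 1. Of 56 called named genes, 16 passed in all 4 of these fits, among them Il17f, Itgae, Foxp3, Ifng, Tbx21 and Prf1, and 15 passed in none, among them Irf1, Tap1, Igtp, Psmb9, Gbp3, Ldlrad4, Tgfbi, Bach2 and Klrg1. None of the 56 changed direction in the 18 settings run for genes. Quantile normalization moved called genes by at most 0.05 on the log2 scale and kept the calls of 316 of 351; among the named genes it ended those of Cxcr5, Ccr7 and Acadl (adjusted p = 0.0502 each). Quantile normalization, median centring, and trend and robust settings called 385, 421 and 382 probe sets, and 303 had a difference of at least 1. Except where noted, the causes of these changes were not tested. Lists were not tested with the random block, the unmoderated test or the added threshold. Camera called 13 to 18 lists with a sample left out, 0 with an estimated correlation, against 16 as reported. Of those 16, 12 were called in all 15 other camera settings at the preset correlation; the memory and stem-like, IL-6 and STAT3, oxidative phosphorylation and pro-apoptotic lists were not. Arrays give no depth, and signal over background could not be judged without detection calls.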

Other observations

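The tests chosen only after the result was seen were those of other cell types as a source, the level-matched random lists, the stricter counts of neighbouring genes, and the tallies by symbol family. Genes were also grouped by symbol stem into families. Of 6 measured Cxcr genes, Cxcr5 was higher and Cxcr1 and Cxcr2 lower in Tc17 (one-sided Fisher's exact test over 594 families, adjusted p = 0.0451). Cxcr1 and Cxcr2, receptors for neutrophil-attracting chemokines, had log2 differences of −2.33 and −2.74. The 20 TNF receptor superfamily genes held 4 that were higher, Tnfrsf13b, Tnfrsf23, Tnfrsf25 and Tnfrsf26, and the 10 Ccr genes 3 that were higher, Ccr4, Ccr7 and Ccr8. The 10 guanylate-binding protein genes held 3 that were lower, Gbp3, Gbp5 and Gbp7. Each of these 3 families had an exact adjusted p of 0.0645 and did not pass. Genes of a family often lie side by side and are not independent.

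Outside the lists and the naming rule, some genes were picked after their values were seen. Tnfsf14, the gene of the TNF family ligand LIGHT, was 9.68-fold higher in Tc17 by intensity, with a Tc1 mean of 5.80 not shown to be above background (limma adjusted p = 0.00481). Nos2, the inducible nitric oxide synthase gene, was 9.32-fold higher and Cd86, the gene of a costimulatory ligand, 7.77-fold higher. Aqp3, a water and glycerol channel gene, was 9.32-fold higher and Muc13, a membrane mucin gene, 11.3-fold higher. The arrays of the groups did not overlap for any of these 5 genes.

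Genes called in the same direction often lay next to each other: 36 adjacent pairs among 21981 ordered genes, against a mean of 3.60 in 10000 permutations of the calls within bins of mean level (p = 1e-04, the smallest they can give), such as Gzmk with Esm1, Ifngr2 with Tmem50b and Gpr15 with Cldnd1, chosen after their values were seen. Random placement is argued against by that p. Probes shared between paralogs of 1 symbol stem do not account for the 30 pairs of different symbol stem, against a mean of 3.43 (permutation p = 1e-04). Paralogs with unlike symbols were not set apart and no probe sequences were compared, so shared probes stay possible for such pairs. Transcripts running on into the next gene cannot be told apart from shared local regulation: pairs that skip an uncalled gene, which run-on should not favour, numbered 8 against 3.30 (permutation p = 0.021), which met the bound set beforehand against run-on, but these are other pairs than the adjacent ones, and their excess of 4.70 is small beside the 26.6 of adjacent pairs. The count was 6 against 3.06 with skipped genes that moved under 0.5 (permutation p = 0.089), 5 against 2.95 without provisional symbols (p = 0.18), and 3 against 2.74 with both limits (p = 0.51). Local control of neighbouring genes therefore may contribute as a hypothesis from the same data, and strand was not tested. Chromosome 16 held more of the 36 adjacent pairs than any other chromosome, all of them higher in Tc17, and this concentration was not tested.

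Ebf1, Lyz2, Ly6g and Foxp3, markers of other cells, were higher in Tc17, although naive CD8+ T cells had been sorted before culture. More B cells, granulocytes or CD4 T cells in the Tc17 than in the Tc1 cultures are argued against by their other transcripts. Differences of these transcripts are set against 3.13 for Ebf1, 2.52 for Ly6g and 3.95 for Foxp3. Cells carried equally into both groups would leave such differences near 0 and are not excluded. Cd4 and Zbtb7b (7.91 in Tc1 and 7.78 in Tc17) lay above every array median in both groups. The median log2 difference of 11 B cell transcripts was 0.0046 (Cd79a 6.05 and 6.06 in Tc1 and Tc17). The fixed markers Cd79b (0.52) and Ighm (0.17, other probe sets −0.16 to 1.46) were not among the 11. Neither was called, and the fixed B cell list, which holds both, had a median of 0.01. For 12 granulocyte transcripts the median was 0.0145 (Csf3r 5.51 and 5.54). For 5 CD4 T cell transcripts it was −0.1284 (SD 0.82, Cd4 7.05 and 6.99), with Izumo1r alone above 0 at 1.57. Macrophages cannot be told apart from expression in the T cells. The median of 15 other macrophage transcripts was 0.38, below the bound of 0.5 times that of Lyz2 (3.53). However, Ctss was called higher and 14 of 15 were above 0 (camera p = 3.06e-07 at the preset correlation and p = 0.149 with an estimated correlation). The 15 left out Cd68, the 1 fixed macrophage marker with a difference below 0 (−0.14). That bound assumes that macrophages hold the other transcripts as abundantly as Lyz2, which was not tested, so it was set aside for macrophages after the values were seen. For the other 3 cell types it was kept, under the same untested assumption. None of the B cell and granulocyte transcripts was called, and 7 of 11 and 7 of 12 were above 0. Of the 5 CD4 T cell transcripts 1, Izumo1r, was called, so the argument against more CD4 T cells in Tc17 is weaker. Expression of Ebf1, Ly6g and Foxp3 by the Tc17 cells themselves may explain these 3. Expression that differs in other cells present in both cultures may do so too. Both are hypotheses that single cells would have to test.

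Interferon-inducible genes lay lower in Tc17 together with Ifng (−5.49), while Ifngr2 lay higher (4.00). The hypothesis of a weaker interferon-gamma response was tested on 26 further interferon-gamma-inducible genes outside the fixed lists. Their median was −0.44, 21 were below 0 and 1, Nlrc5 (−1.37), was called lower. Those above 0 were Irf8 (0.01), Irf9 (0.18), Psme2 (0.20), Cxcl9 (0.01) and Cxcl10 (0.01). Gbp6, Gbp8, Gbp9, Gbp10 and Gbp11, all below 0, belong to the family of the called Gbp3 and Gbp7 and are not independent of them. Camera gave p = 9.71e-09 at the preset correlation and p = 0.119 with an estimated correlation. The test with an estimated correlation uses the few residual degrees of freedom of the fit, which raises its p-values whatever the correlation. Most of the values therefore go with the hypothesis, but the set test passed at the preset correlation only. The estimated correlation among these 26 genes was 0.197, so correlation among them raises that p-value too. The share of correlation in the loss of the call was not tested. A shift of array values that depends on a gene's level is argued against for the 49 genes of the fixed and the further list together (median −0.42), since 0% of 10000 level-matched random lists had a median as low (lowest −0.11). Many of these genes also respond to other interferons, so the response may involve those too, which was not tested.

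Among the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 2318 probe sets and the highest of the others called 0. With 10 splits no share under 0.05 can be reached. Technical arrays counted as samples here, and every other split mixes Tc1 with Tc17, so that their difference adds to the spread within groups.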
